A study of Mus musculus with 6 samples.

How the data were processed

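The samples were cardiomyocytes of newborn mice, isolated on postnatal day 1. Per the labels' protocols, hearts were digested with pancreatin and collagenase, cardiomyocytes were enriched by magnetic sorting with a neonatal isolation system, and the cells were plated in medium with 5% horse serum and 10% fetal bovine serum. After 48 hours the medium was replaced and the cells were kept without serum for 24 hours. RNA was extracted and 100 ng of total RNA went into QuantSeq 3' mRNA libraries in the forward orientation, a method that reads a tag near the polyadenylated end of each transcript. The count of a gene therefore depends on its 3' end and not on its length, and a deletion elsewhere in a gene need not change its count.

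The labels give 2 genotypes with 3 libraries each, called control and GR-cKO here, where GR-cKO stands for deletion of the glucocorticoid receptor in cardiomyocytes. They call the libraries biological replicates but do not say whether they came from separate animals, litters or cultures. The p-values therefore measure only the spread between these libraries, which may be partly technical. Groups and replicate numbers were taken from the sample titles.

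The authors deposited raw counts per gene, whole numbers without normalization, in 1 table per library. Per the submitters' processing notes, the tools named were bcl2fastq, cutadapt 1.16, FastQC 0.11.7, MultiQC 1.5, STAR 2.5.4a, featureCounts 1.6.2 and DESeq2 1.18.1, with the mouse build GRCm38. The strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Genes that overlap another gene, or that have close copies or processed pseudogenes (Gapdh, Pgk1, Ldha and the alpha- and beta-globin genes among those named), are therefore uncertain.

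Each table held 52649 rows, of which 52550 were Ensembl genes, 92 were ERCC spike-in RNAs and 7 were SIRV spike-in RNAs. The spike-in rows took 1.98% to 2.36% of all counts in a library and stayed out of library sizes and tests. Gene identifiers were matched to GENCODE release M21, which uses GRCm38. It gave a symbol, biotype and coordinates for 52403 of them. The 147 unmatched identifiers held at most 0.0077% of the gene counts of a library. Coordinates are 1-based.

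Gene counts summed to between 19371508 and 22583596 per library. A count of 0 in a library of this size allows a level of up to 0.133 to 0.155 CPM, taken as 3 counts. This floor covers counting error only. The pairs of libraries within a group differed by more than sampling noise, with a median chi-square of 2.48 to 3.70 per gene over 14301 genes, so all 6 were counted as separate libraries.

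The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) of GR-cKO against control with TMM factors, after its default filter on low counts, with Benjamini-Hochberg adjustment over the 14386 genes tested and a threshold of 0.05. Levels are CPM scaled by the TMM factors, which lay between 0.980 and 1.024, given as mean ± SD over 3 libraries. Fold changes are on the log2 scale, GR-cKO over control, with a standard error taken from the fold change and its F statistic. The common biological coefficient of variation was 0.128. On counts simulated for this comparison with 200 changed genes, the test called 8% of the genes changed 1.25-fold, 62% of those changed 1.5-fold, 82% at 2-fold and 92% at 3-fold, with 14105 genes tested. It called 8 of 13908 unchanged genes, and none of 14115 when no gene was changed.

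Gene lists were written down before the data were examined and cover glucocorticoid targets and signalling, the cell cycle, the sarcomere, cardiomyocyte maturation, excitability, energy metabolism, stress and signalling responses, and markers of atrial, ventricular and other heart cell types. Each list with at least 5 tested members (30 lists, sex-linked genes not among them) was tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the lists. For each list, the members past the threshold over all genes are given beside the number adjusted over the list alone. A list's p with an estimated correlation is given where it ends the call.

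The rule for named genes was also fixed before the data were examined. It took Nr3c1, then the 10 largest increases and 10 largest decreases among genes past the threshold with at least 5 CPM in the higher group and no overlap between the groups. Genes named only Gm or Rik and pseudogenes were left out of these. It then took up to 4 members of each list with the smallest p, or 2 members as values only where none passed. Of the genes so chosen, only part is printed, and single members of the cholesterol synthesis list are not reported here. A few others are named as examples or because a list's best-known members did not pass, and these were chosen after their values were seen: Fkbp5, Tsc22d3, Sgk1, Klf9, Ldha, Pdk1, Gapdh, Pgk1, Gdf15, Tcap, Dcn, Npr3, Dbp, Tbx5, Upk3b, Kdm5d, and Cpt1b with the other genes listed at or near 0. After seeing the data, 6 further lists were chosen and tested the same way, with adjustment over these 6: targets of hypoxia-inducible factor, imprinted genes, chaperones of the endoplasmic reticulum, p53 targets, NRF2 targets, and genes of the insulin-like growth factor and ERBB pathways. Their members were named after their values were seen.

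Alternatives fixed in advance were other scalings (DESeq2's size factors, upper quartile, library size), no filter or a stricter filter of at least 1 CPM in each library of a group, DESeq2 1.42.0, limma-voom, a robust fit, the replicate number as a block, a test against a fold of 1.2, thresholds of 0.1 and 0.01, removal of mitochondrially encoded genes, and each library left out in turn. For the lists they were an estimated correlation, the rotation test fry and a prior count of 0.5. Chosen after seeing the data were scaling by the ERCC totals, removal of genes on chromosomes X and Y, and removal of Gm42418 with the mitochondrial rRNA genes. Gm42418, a locus that overlaps a ribosomal RNA sequence, took 6.15% to 8.57% of gene counts.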

Results

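Messenger RNA was counted at its 3' ends in cultured cardiomyocytes from newborn mice, from 3 control libraries and 3 GR-cKO libraries, in which the glucocorticoid receptor had been deleted in cardiomyocytes. This receptor, encoded by Nr3c1, is the transcription factor through which cortisol and corticosterone act. The design asked which genes differ in expression between cardiomyocytes with and without it after a period in culture. The libraries held 19371508 to 22583596 gene counts each, with means of 20592144 in control and 20818895 in GR-cKO, so depth was similar in both groups. At this depth 18364 to 19242 genes had a count in a library.

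Nr3c1 (ENSMUSG00000024431, GRCm38 chromosome 18, 39410545 to 39519421, minus strand) was lower in the GR-cKO libraries. It stood at 71.5 ± 2.95 CPM in control and 44.4 ± 1.7 CPM in GR-cKO (SD, n = 3 each), a log2 fold change of -0.69 ± 0.09 (SE; edgeR quasi-likelihood test, adjusted p = 3.3e-06). The 3 GR-cKO libraries, at 46.2, 42.8 and 44.1 CPM, all lay below the 3 control libraries, at 68.2, 73.9 and 72.4 CPM. The labels do not name the deleted exon. A 3' tag outside the deleted part need not change with the deletion, so the remaining counts do not measure how much functional receptor was left. No member of a list of other glucocorticoid signalling components passed the test among 13 measured, nor did any when adjusted over the list alone. Its members with the smallest p were Hsd11b1, which regenerates active glucocorticoid, with a log2 fold change of 0.70 ± 0.29, and the receptor coactivator Ncoa1, at 22.2 ± 0.409 and 27.1 ± 3.91 CPM in control and GR-cKO.

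Expression differed widely between the genotypes. Genes of glycolysis were higher in GR-cKO, while genes of cell division and cholesterol synthesis were lower. Of 14386 genes tested, 2132 passed the threshold (edgeR quasi-likelihood test, adjusted p below 0.05), 1097 higher and 1035 lower in GR-cKO. Scaling by the ERCC spike-ins, chosen after seeing the data, gave 1355 higher and 522 lower, so the balance between rises and falls depends on the scaling. A change of at least 2-fold was found for 272 of the higher and 186 of the lower genes. The groups did not overlap in 2066 of the 2132 genes, and in 29.9% of all tested genes, where chance gives 10%. The controls contained Xist and the GR-cKO libraries almost none. Without the genes on chromosomes X and Y, left out after seeing this, 2060 genes passed. Leaving them out does not remove effects of sex on genes of other chromosomes, which cannot be told apart from genotype in these libraries.

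The 10 largest increases among genes with at least 5 CPM in the higher group ranged from 2.81 to 6.41 on the log2 scale. Ndufa4l2, a mitochondrial protein induced by hypoxia, rose from 0.382 ± 0.238 to 33.3 ± 4.03 CPM (n = 3 each; log2 fold change 6.41 ± 0.25, adjusted p = 3.84e-15). Car9, a carbonic anhydrase at the cell surface, had a log2 fold change of 4.85 ± 0.36 and Mgarp, a mitochondrial protein, one of 4.13 ± 0.32. Egln3, an oxygen-dependent prolyl hydroxylase that marks hypoxia-inducible factor for degradation, rose 11.4-fold, from 20.5 ± 2.55 to 233 ± 13.6 CPM, and Bnip3, a receptor for mitochondrial autophagy, 7.43-fold. The other genes in this group of 10 were the potassium channel subunit Kcne3 (4.87), Kbtbd11 (3.97), the ubiquitin ligase Rnf208 (3.34), the incretin receptor Gipr (3.27) and the metallothionein Mt2 (2.81), given as log2 fold changes. Kcne3, Car9, Ndufa4l2, Mgarp, Kbtbd11 and Rnf208 were all below 1 CPM in control, so the size of their fold changes is less certain than their direction.

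Under the same limit of 5 CPM in the higher group, the 10 largest decreases were Xist and 9 genes with log2 fold changes between -2.22 and -1.65. Efemp1, a matrix protein of the fibulin family, fell from 24.1 ± 3.48 to 5.18 ± 1.01 CPM (log2 fold change -2.22 ± 0.17, adjusted p = 1.5e-09), and Dlk1, an imprinted inhibitor of differentiation, from 94.3 ± 11.8 to 20.3 ± 3.14 CPM (-2.21 ± 0.11, adjusted p = 1.2e-12; n = 3 each, edgeR). Kcnj3, a subunit of the atrial acetylcholine-activated potassium channel, was 3.25-fold lower. Also among the 10 were the RNA-binding protein gene Elavl2 (log2 fold change -1.74), the glycine-cleavage enzyme gene Gldc (-1.74), the cohesin acetyltransferase gene Esco2 (-1.72), Serpinb9b (-1.72), the imprinted gene Nnat (-1.67) and the guidance factor gene Sema3a (-1.65).

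**Figure D1:**
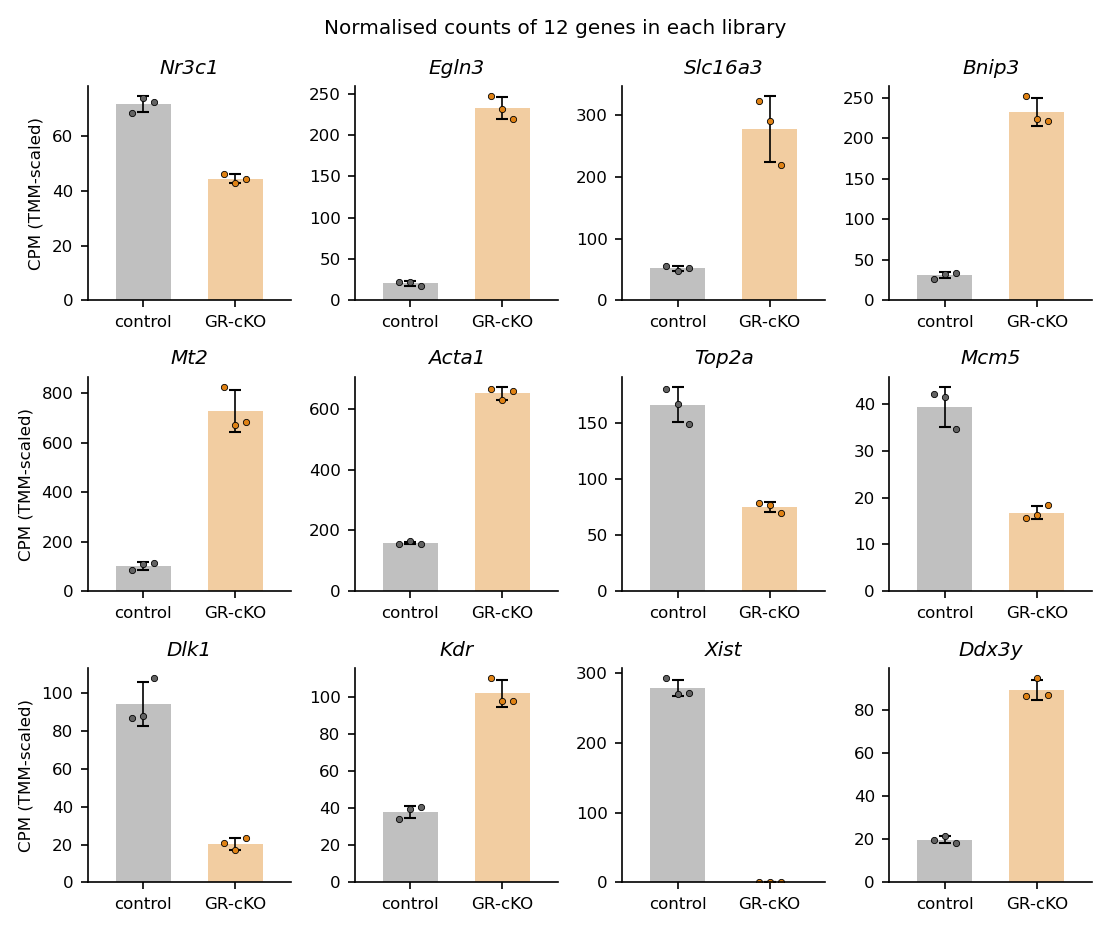
TMM-scaled CPM (vertical axis, linear from 0) of 12 genes in the 3 control and 3 GR-cKO libraries. Points are libraries, bars are group means and whiskers are 1 SD. In each panel the groups do not overlap; Egln3 rose from 20.5 to 233 CPM and Top2a fell from 166 to 75.1 CPM.

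Genes of cell division were lower throughout. All 27 members of the mitosis list fell (27 also when adjusted over the list alone), with a median log2 fold change of -1.0 (camera adjusted p = 3.36e-25, and 0.00823 with an estimated correlation). Top2a, which untangles chromosomes, fell from 166 ± 15.6 to 75.1 ± 4.55 CPM (log2 fold change -1.14 ± 0.08, adjusted p = 4.65e-10), and the mitotic kinases Cdk1 and Aurka fell 1.91-fold and 2.34-fold. In the DNA replication list 27 of 30 members fell and none rose (30 fell when adjusted over the list alone; median -0.94, camera adjusted p = 1.12e-22, and 0.0116 with an estimated correlation). Subunits of the replicative helicase were among them, with Mcm5 at 39.3 ± 4.19 CPM in control and 16.8 ± 1.47 CPM in GR-cKO and Mcm7 at 78.1 ± 6.7 and 36.2 ± 0.45 CPM. Cell cycle inhibitors did not move as a group (2 higher, 3 lower of 20; 4 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.414). Cdkn1a (p21) and Btg2 rose, by 0.53 ± 0.07 and 0.85 ± 0.09 on the log2 scale, while Cdkn1c (p57) and Cdkn2c (p18) had log2 fold changes of -0.77 ± 0.12 and -1.15 ± 0.24.

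Glycolysis genes rose in GR-cKO. Of 26 members, 17 were higher and none lower (18 higher when adjusted over the list alone), with a median log2 fold change of 0.81 (camera adjusted p = 1.3e-12, and 0.0116 with an estimated correlation). The lactate exporter Slc16a3 rose 5.35-fold, from 51.9 ± 4.08 to 277 ± 53.5 CPM, the glucose transporter Slc2a1 3.32-fold and hexokinase Hk2 2.52-fold (n = 3 each). Ldha, which makes lactate, had a log2 fold change of 0.87 ± 0.07, and Pdk1, which restrains entry of pyruvate into mitochondria, one of 1.46 ± 0.09.

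Few genes of mitochondrial pathways passed the test. Of 75 nuclear genes of oxidative phosphorylation 2 rose and none fell (1 and none when adjusted over the list alone). The median was 0.05, and 0.14 with ERCC scaling (camera adjusted p = 0.108). This list did pass the camera threshold without GR-cKO replicate 1. Ndufv3 was at 177 ± 3.52 and 228 ± 3.2 CPM. Of 27 fatty acid oxidation genes 1 rose and 1 fell, the same numbers as adjusted over the list alone (median -0.06, and 0.04 with ERCC scaling; camera adjusted p = 0.813); the riser was Lpl, a lipase that supplies fatty acids, at a log2 fold change of 0.41 ± 0.06. Of 20 genes of the TCA cycle and pyruvate dehydrogenase 1 fell and none rose, and none passed when adjusted over the list alone (camera adjusted p = 0.971). Of 25 genes of mitochondrial biogenesis and dynamics 3 rose and none fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.281); Bnip3 and its paralogue Bnip3l (0.69 ± 0.10) act in mitochondrial autophagy rather than biogenesis. Among 8 measured mitochondrially encoded genes 2 fell and none rose (4 fell when adjusted over the list alone), with mt-Co1 at 1117 ± 6.25 and 867 ± 22.1 CPM. Their median was -0.20, and -0.11 with ERCC scaling, where 1 member fell. The camera adjusted p was 0.0346. This call ended with an estimated correlation (adjusted p = 0.149), and without control replicate 1 (0.0606), control replicate 2 (0.0789) or GR-cKO replicate 1 (0.101). Mitochondrial rRNA took 2.6% ± 0.157 of gene counts in control and 2.0% ± 0.203 in GR-cKO (exact permutation test, two-sided, p = 0.1, the smallest that 3 libraries against 3 allow). Cpt1b, mt-Co2, mt-Co3, mt-Atp8 and mt-Nd4l were listed at 0 in all libraries, although heart cells use them, so their values say nothing about expression.

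Sarcomere genes were mostly higher. Of 30 members 21 rose and 2 fell (23 and 4 when adjusted over the list alone), with a median log2 fold change of 0.31 (camera adjusted p = 2.34e-07; adjusted p = 0.0547 with an estimated correlation). Skeletal alpha-actin Acta1 rose 4.09-fold, from 159 ± 4.14 to 650 ± 20.3 CPM, and the actin-binding protein gene Xirp2 4.99-fold. The Z-disc gene Csrp3 and the intermediate filament gene Des rose 2.07-fold and 1.96-fold. Those that fell were the atrial light chain Myl7 (log2 fold change -0.71 ± 0.06) and Tcap (-0.65 ± 0.07). Lists of postnatal maturation genes (5 higher, 7 lower of 21, the same when adjusted over the list alone; camera adjusted p = 0.516), fetal cardiomyocyte genes (8 higher, 2 lower of 19; 8 and 5 when adjusted over the list alone; camera adjusted p = 0.162) and calcium handling and excitability genes (7 higher, 5 lower of 25; 9 and 6 when adjusted over the list alone; camera adjusted p = 0.516) held changes in both directions. The calcium pump Atp2a2 fell from 1974 ± 58.3 to 1456 ± 19 CPM and its inhibitor Sln from 318 ± 17.9 to 175 ± 10.4 CPM. The adult myosin Myh6 rose from 4364 ± 169 to 5686 ± 96.8 CPM and natriuretic peptide Nppa from 13621 ± 140 to 18229 ± 466 CPM (n = 3 each). The median and mean of the calcium list differed in sign, at 0.15 and -0.05.

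Genes that glucocorticoids are known to induce were more often higher than lower in GR-cKO. Of 33 members 17 rose and 1, Cdkn1c, fell (20 and 1 when adjusted over the list alone), with a median log2 fold change of 0.34 (camera adjusted p = 2.47e-07; adjusted p = 0.0517 with an estimated correlation). Mt2 rose from 104 ± 15.6 to 728 ± 84 CPM and Mt1 from 155 ± 11.3 to 764 ± 37.6 CPM (n = 3 each). These metallothioneins also respond to metals and stress, and Lcn2, at a log2 fold change of 1.49 ± 0.20, also responds to inflammation. Sgk1 and Klf9 had log2 fold changes of 0.37 ± 0.09 and 0.32 ± 0.08, both past the threshold. Fkbp5, at 21.9 ± 1.03 and 20.9 ± 2.82 CPM, and Tsc22d3, at 45.5 ± 2.51 and 54.3 ± 1.74 CPM, did not pass over all genes. When adjusted over the list alone, Tsc22d3 was higher (log2 fold change 0.26) and Fkbp5 still did not pass.

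Several signalling and stress lists were higher. Of 20 integrated stress response genes 16 rose and none fell (17 and 1 when adjusted over the list alone; median 0.56, camera adjusted p = 2.22e-10; adjusted p = 0.0543 with an estimated correlation). The pseudokinase gene Trib3 rose from 10.6 ± 2.49 to 47.4 ± 3.34 CPM, the amino acid transporter gene Slc7a5 2.7-fold and the stress hormone gene Gdf15 2.28-fold. Of 20 immediate early genes 12 rose and none fell (15 and 2 when adjusted over the list alone; median 0.43, camera adjusted p = 5.83e-06; adjusted p = 0.0547 with an estimated correlation), with Atf3 at 7.09 ± 0.361 and 20.5 ± 1.53 CPM. Of 18 circadian clock genes 8 rose and none fell (9 and 1 when adjusted over the list alone; median 0.39, camera adjusted p = 2.58e-05; adjusted p = 0.0504 with an estimated correlation). They included the repressor genes Bhlhe40 (2.3-fold) and Bhlhe41 (1.95-fold), which are also known to respond to hypoxia, and the output gene Dbp, at a log2 fold change of 0.76 ± 0.17.

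Cholesterol synthesis genes fell. Of 20 members 14 were lower and none higher (18 lower when adjusted over the list alone), with a median log2 fold change of -0.50 (camera adjusted p = 4.82e-10, and 0.0156 with an estimated correlation). Other lists did not pass. They were YAP target genes (2 higher, 5 lower of 19; 3 and 5 when adjusted over the list alone; camera adjusted p = 0.162), inflammatory genes (2 higher, 3 lower of 17; 4 and 4 when adjusted over the list alone; camera adjusted p = 0.866), interferon-stimulated genes (none of 18, nor when adjusted over the list alone; camera adjusted p = 0.811) and cytosolic ribosomal protein genes (none of 50, nor when adjusted over the list alone; camera adjusted p = 0.811). With ERCC scaling the balance turned in the YAP list (3 higher, 1 lower) and the inflammatory list (4 higher, 1 lower). Csf1, a growth factor for macrophages, fell from 253 ± 8.79 to 180 ± 5.32 CPM, while the YAP target Ankrd1 rose from 8852 ± 247 to 11563 ± 187 CPM.

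**Figure D2:**
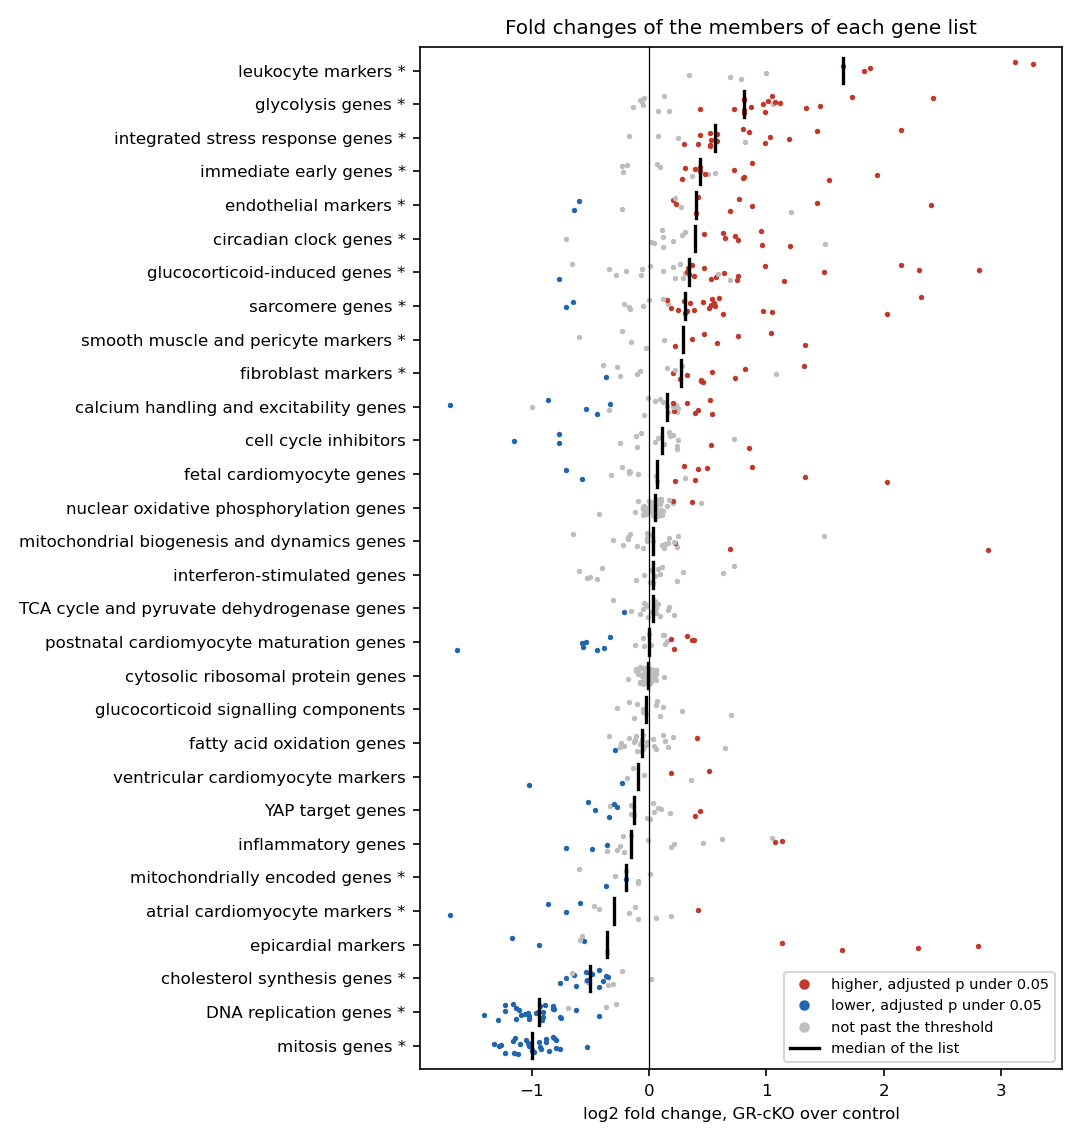
Log2 fold change (horizontal axis, GR-cKO over control) of each tested member of the 30 gene lists that were tested. Red and blue points passed an adjusted p of 0.05 upwards and downwards, grey points did not, black lines are list medians and asterisks mark the 15 lists past the camera threshold. The mitosis members all lie below 0 around a median of -1.0, and glycolysis members reach 2.42.

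Markers of other heart cell types also differed, although the cells had been sorted for cardiomyocytes. Of 20 fibroblast markers 10 rose and 1, Dcn, fell (11 and 4 when adjusted over the list alone; median 0.27, camera adjusted p = 0.00185; adjusted p = 0.0578 with an estimated correlation). The matrix genes Postn (67 ± 0.885 to 167 ± 9.5 CPM) and Col1a1 (1385 ± 58.4 to 1911 ± 12.9 CPM) were among those that rose. Of 15 endothelial markers 9 rose and 2, Emcn and Npr3, fell (9 and 3 when adjusted over the list alone; median 0.40, camera adjusted p = 0.000448; adjusted p = 0.0547 with an estimated correlation), with Kdr, a receptor for vascular endothelial growth factor, at 37.9 ± 3.46 and 102 ± 7.28 CPM and Fabp4 at 14.8 ± 4.04 and 77.5 ± 9.25 CPM. Of 12 smooth muscle and pericyte markers 7 rose and none fell (7 and 2 when adjusted over the list alone; median 0.29, camera adjusted p = 0.00573; adjusted p = 0.182 with an estimated correlation), Cnn1 by 1.33 ± 0.08. Of 16 leukocyte markers only 9 had enough counts to be tested. Of these 9 markers 5 rose and none fell, the same as adjusted over the list alone (median 1.65, camera adjusted p = 0.000119, and 0.12 with an estimated correlation). They were scarce, with Lyz2 at 12.9 ± 2.25 and 40.6 ± 9.66 CPM and Tyrobp at 0.195 ± 0.149 and 1.72 ± 0.41 CPM. A scarce gene can pass the filter through 1 group alone, so the median may be too high.

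Epicardial markers split, with 4 higher and 3 lower of 11 (4 and 4 when adjusted over the list alone; camera adjusted p = 0.984). The keratin genes Krt8, Krt18 and Krt19, which other epithelia and stressed cells also express, rose by 2.80 ± 0.28, 1.64 ± 0.09 and 2.29 ± 0.14 on the log2 scale, and Tbx18 and Upk3b had log2 fold changes of -0.55 ± 0.09 and -1.17 ± 0.22. The list's median was -0.36 and its mean 0.30. Atrial markers were lower as a list (1 higher, 4 lower of 12; 1 and 5 when adjusted over the list alone; median -0.30, camera adjusted p = 0.00423; adjusted p = 0.076 with an estimated correlation). Myl7, Sln, Kcnj3 and Tbx5 fell and Nppa rose. Ventricular markers did not pass (2 higher, 2 lower of 8; 3 and 2 when adjusted over the list alone; camera adjusted p = 0.866), with Myl3 at 8010 ± 557 and 11402 ± 1127 CPM. Only 2 erythroid markers and 3 neural or Schwann cell markers could be measured, too few for a list test, and none passed over all genes, while 1 erythroid marker was higher and 1 neural marker lower when adjusted over the list alone. Hbb-bs was at 1.56 ± 0.815 and 2.5 ± 0.818 CPM and Dbh at 13.6 ± 2.27 and 9.3 ± 2.29 CPM.

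The groups differed in sex-linked RNA. Xist, the X-chromosome RNA of female cells (GRCm38 chromosome X, 103460366 to 103483254), had 17404 counts over the 3 control libraries and 2 over the 3 GR-cKO libraries, a ratio of 8588 (95% counting interval 2377 to 70912). The 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d all rose in GR-cKO, and with Xist all 5 listed genes passed, also when adjusted over the list alone. Ddx3y was at 19.8 ± 1.5 CPM in control and 89.3 ± 4.73 CPM in GR-cKO (log2 fold change 2.17 ± 0.10, adjusted p = 6.6e-14). Summed, the 4 genes stood at 27.1 ± 1.43 and 122 ± 7.46 CPM (n = 3 each). The sex of the pups is not given in the labels, and the difference runs parallel to genotype in all 6 libraries, so it stands beside each of the gene groups above.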

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

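The tests in this part were chosen after the counts had been seen. Each table also held counts of spike-in RNAs, synthetic transcripts added in known amounts, which the labels do not mention. The ERCC RNAs took 1.159% and the SIRV RNAs 1.036% of all counts on average over the 6 libraries, well above what a count of 0 allows. The ERCC share was 1.21% ± 0.0462 in control and 1.11% ± 0.055 in GR-cKO, and the SIRV share 1.08% ± 0.0292 and 0.989% ± 0.0461 (SD, n = 3 each; exact permutation test, two-sided, p = 0.1 for each, the smallest this design allows). Expressed as log2 of scaled gene counts per ERCC count, the groups stood at 6.35 ± 0.07 and 6.45 ± 0.07, a difference of 0.09 (exact permutation test, n = 3 each, p = 0.2). Per SIRV count the difference was 0.10. The step at which they were added is not given in the sources used here.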

How the results depend on the processing

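The ERCC scaling and the removal of X and Y genes or of Gm42418 with mitochondrial rRNA were chosen after seeing the data. Nr3c1 stayed lower and past the threshold in all 17 alternatives run for it, between -0.72 and -0.59 on the log2 scale. No gene called in the main test was called in the opposite direction in any alternative. The count of 2132 changed genes lay between 1572 and 1879 with 1 library left out, where fewer libraries are tested. It was 2133 with DESeq2's size factors, 2111 with upper-quartile factors, 2192 by library size (964 higher, 1228 lower, so the balance turned), 2239 without a filter, 2091 with DESeq2 and 2155 with limma-voom. It moved by more than 1.5 times in 2 settings that raise the bar by construction. These were the test against a fold of 1.2, with 948 genes (519 higher, 429 lower), and a threshold of 0.01, with 1308 (716 higher, 592 lower). ERCC scaling gave 1877 genes, 1355 higher and 522 lower; it shifts the median gene by 0.09 upwards, which moves small decreases out of the calls. Of 110 named genes that passed, 97 kept direction and call in each of up to 17 alternatives run for single genes and 13 lost the call in at least 1; the fold of 1.2 and the other thresholds were not run for single genes. No clear pairing by replicate number was seen: residuals of same-numbered libraries correlated over genes at 0.01, -0.04 and 0.14. The residuals are centred within groups of 3 libraries, so this check cannot exclude a pairing. Adding the number as a block gave 2353 genes (1201 higher, 1152 lower), while the correlation of other pairs reached 0.24.

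Of 15 lists past the camera threshold, 4 held with an estimated correlation (mitosis, DNA replication, glycolysis and cholesterol synthesis), while the other 11 had adjusted p of 0.0504 to 0.182. The rotation test fry, which does not compare a list with other genes, passed 19 lists. Those it added were postnatal maturation genes downwards (fry adjusted p = 0.0273) and fetal cardiomyocyte genes upwards (fry adjusted p = 0.000208). It also added mitochondrial biogenesis and dynamics genes (fry adjusted p = 0.00445) and epicardial markers (fry adjusted p = 0.00642), both upwards. The list of mitochondrially encoded genes lost its call with the replicate block (adjusted p = 0.0671) and without control replicate 1 (0.0606), control replicate 2 (0.0789) or GR-cKO replicate 1 (0.101). No other list lost its call when a library was left out. At this depth and spread, 62% of simulated 1.5-fold changes were called, in a simulation with 200 changed genes. In the data 2132 genes passed, which makes the Benjamini-Hochberg threshold on unadjusted p less strict than in that simulation. The simulated share may therefore be too low for the data, where called genes had a median absolute log2 fold change of 0.56. Small changes can still have been missed, but how often was not tested.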

Other observations

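The 6 gene lists that open this part were chosen after the data had been seen, and so were the tests of cardiomyocyte share, GC content, sex-linked counts, the remaining glucocorticoid-induced genes and the neighbours of Nr3c1, although the camera tests of fibroblast, endothelial and glucocorticoid-induced genes were themselves planned. Genes that hypoxia-inducible factor (HIF) is known to induce, none of which had been looked at or belonged to an earlier list, were higher in GR-cKO. Of 37 tested members 27 rose and 1, Cited2, fell, with a median log2 fold change of 0.83 (camera adjusted p = 1.68e-14). The angiogenic factor Vegfa rose from 64.9 ± 3.04 to 139 ± 8.78 CPM, the adenylate kinase Ak4 from 12.7 ± 3.04 to 50.6 ± 7.85 CPM and Egln1, an oxygen-sensing hydroxylase, from 77.4 ± 4.39 to 175 ± 6.73 CPM (n = 3 each). Other well-known targets did not pass, such as Adm at 57.2 ± 2.68 and 53 ± 3.88 CPM and Plod2 at 120 ± 3.41 and 116 ± 5.68 CPM. Chaperones of the endoplasmic reticulum fell, 14 lower and none higher of 22 (median -0.40, camera adjusted p = 9.45e-08), with Calr at 894 ± 42.7 and 514 ± 19.3 CPM and Hspa5 at 1331 ± 67.3 and 976 ± 32.6 CPM.

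Imprinted genes were lower as a list, 11 lower and 1 higher of 25 (median -0.28, camera adjusted p = 0.000203). Of these members 3 also belong to other lists. The imprinted list kept Dlk1 and Nnat, already seen among the largest decreases, and Cdkn1c, already seen to fall. Its p therefore rests partly on genes seen before the list was chosen. Besides Dlk1, Mest fell from 667 ± 22.7 to 368 ± 28.9 CPM and Meg3 from 550 ± 31.9 to 433 ± 17.6 CPM, while H19 rose from 2601 ± 66.6 to 3015 ± 123 CPM and Igf2, at 700 ± 17.8 and 660 ± 15.3 CPM, did not pass. The lists of HIF targets, chaperones and imprinted genes had an adjusted p of 0.0426 each with an estimated correlation, and of 0.0737 to 0.11 without any 1 of the 6 libraries. Lists of p53 targets (4 higher, 1 lower of 20; camera adjusted p = 0.243), NRF2 targets (2 higher, none lower of 20; 0.696) and insulin-like growth factor and ERBB pathway genes (5 higher, 4 lower of 20; 0.247) did not pass, although Igfbp7 rose from 247 ± 17.5 to 738 ± 67.8 CPM and Nrg1 fell from 59.6 ± 3.2 to 38.1 ± 1.54 CPM.

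Cell division genes fell while glycolysis genes rose in GR-cKO, with medians 1.81 apart on the log2 scale. A higher share of cardiomyocytes, with fewer dividing fibroblasts and endothelial cells, would lower the markers of both these cell types. Both marker lists were instead past the camera threshold upwards (the higher of the 2 adjusted p was 0.00185, although neither held with an estimated correlation). Sarcomere genes rose as well (21 higher and 2 lower of 30, camera adjusted p = 2.34e-07, and 0.0547 with an estimated correlation). Marker levels can change by regulation as well as by cell share, so they cannot decide this question. A bias by GC content is argued against as the whole cause, since the gap was still 1.74 after the trend of fold change on the GC content of the last 500 bases had been removed. A stronger HIF response in the GR-cKO cultures is consistent with the HIF target list (adjusted p = 0.0426 with an estimated correlation), but that p lay between 0.0737 and 0.11 with any 1 library left out, where the preset correlation gave at most 3.16e-12. Whether such a response would come from the deletion, the sex of the cells, or oxygen and density in the dishes stays open, because the labels give no culture batch.

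Xist and Y-linked RNA differed between the groups, as if the GR-cKO libraries came from male cells and each control library from a mixture. Summed Y-linked counts in control were 22.1% of the GR-cKO level, and Xist varied by only 4.33% (coefficient of variation) over the control libraries. Control libraries from separate sets of pups with different sex mixes are argued against, since the SD of Xist lay at percentile 44 and that of the summed Y-linked counts at percentile 22.6 among genes of like abundance. A shared pool of cells for the 3 control libraries, or separate pools of the same mix, may account for this, and was not tested. The GR-cKO libraries, with 0, 2 and 0 Xist counts, leave a shared pool open as well. If each group came from 1 pool, the p-values would measure technical spread within a pool and not the spread between animals of a genotype. For the 2060 calls outside chromosomes X and Y, sex and genotype cannot be told apart, because both differ between the same libraries; 14% of tested genes on X and 14.8% of those outside X and Y passed.

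Genes that glucocorticoids induce were more often higher than lower in GR-cKO cultures, whose cardiomyocytes should lack the receptor. The camera call of this list ended with an estimated correlation (adjusted p = 0.0517). Markers of other cell types were present, and the cells had been without serum for 24 hours. Whether a ligand of the receptor was present was not tested, so these genes need not have fallen. That members of other lists or of the HIF-type response (Per1, Mt1, Mt2, Ddit4, Cdkn1a, Cdkn1c, Pdk4, Angptl4 and Irs2) carried the whole rise is argued against by the remaining 24 members. Of these 10 rose (median 0.32, unadjusted camera p = 2.2e-05, and unadjusted p = 0.00926 with an estimated correlation). That none of the 24 fell carries no weight, because Cdkn1c, the only member of the whole list to fall, was set apart. Members of the HIF-type response were picked by hand, so some may remain among the 24. The rise of the whole list was known before these 24 were set apart. Lcn2, which also responds to inflammation, stayed among them, so other stress responses are not argued against. Other pathways that induce the same genes may stand behind the rise, which was not tested.

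Only 10 splits of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. As many genes as in the real split, 2132, were found in 1 of the 10, the real one, and the highest of the others gave 0 with edgeR. Each of the other splits mixed control and GR-cKO libraries on both sides, which widens the spread within a side. Their 0 is therefore not the level of calls in data without a difference. At an unadjusted p under 0.05 the others gave 203 to 651 genes and the real split 3756. The splits were run with edgeR alone. Within 10 Mb of Nr3c1 on chromosome 18, 14 of 138 tested genes passed, or 10.1% against 14.9% elsewhere (Fisher's exact test, two-sided, p = 0.147).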
